A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

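Total RNA of strain BY4742 was hybridised to 3 two-colour yeast oligonucleotide arrays, per the labels with cells of the 4th, 7th or 11th generation in Cy3 and cells of the 1st generation in Cy5. Cells had been labelled with biotin and grown in rich medium at a temperature given in the labels. How the 1st generation cells were obtained, and whether 1 RNA preparation served all 3 arrays, is not stated. Each generation was measured on 1 array.

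Each array file holds, per the file headers, the raw intensity of every spot in both channels without background subtraction. The authors then subtracted 1 constant per channel and array, which the values give as 27.2, 22.2 and 25.3 for Cy5 and 47.4, 41.4 and 45.0 for Cy3, and left an intensity empty where the result was near or below 0. The authors multiplied each Cy3 intensity by 1 factor per array, 0.340, 0.324 and 0.270, so that the median ratio is 1. The deposited ratio is Cy3 over Cy5 of these scaled signals, and the authors marked ratios of at least 2 as up and of at most 0.5 as down. The deposited series table holds the log2 of that ratio, equal to the array files within 5e-08.

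The raw intensities were used. An array carries 6272 spots in 16 print blocks of 392 spots, among them 5792 features for yeast genes, 320 blank spots, 8 spots for ACT1, 72 negative controls, 60 spots without a probe and 18 quality control spots. Features were matched by systematic name to the gene table of the reference annotation; 5730 matched, 92 symbols were updated, and 35 features that name several loci were kept out of the named genes. No genome coordinates were used apart from the order of genes along chromosome arms. Intensities were corrected with the normexp method with an offset of 50, which estimated the background from the signals of all spots of the channel. They were then normalised by loess within each array in limma 3.58.1 under R 4.3.3, with control spots at weight 0. Spots of one feature were averaged, and log2 of Cy3 over Cy5 was taken, so that positive values mean more transcript in the older cells. A feature counted as above background when its raw signal exceeded the mean plus 2 SD of the 320 blank spots, which was 32.2, 26.4 and 29.6 in Cy5 and 56.6, 70.5 and 51.3 in Cy3. The wider limit of the 7th generation Cy3 channel comes with an SD of 14.5 among its blanks, 1 of which reached 294. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

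The comparisons, filters, gene lists, named-gene rule and first set of alternatives were fixed before the data were examined. Each older generation was compared with the 1st on its own array, and generations were compared with each other by the difference of their log2 ratios. With 1 array per generation no generation can be tested on its own; a pooled test of the older cells against the 1st generation, or of a trend with generation, over the 3 arrays was not run. Features with signal above background in at least one channel (of both arrays for a difference) were counted when at least 2-fold higher or lower, and no p-value was computed for any gene. The range between arrays can be judged from the difference of the 7th and 4th generation ratios, whose SD across features was 0.178; since it holds real differences too, it is not a replicate error. The 1st generation signal differed at least 2-fold between some pair of arrays for 131 features, 2.26% of all.

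In all 52 gene lists were tested in 6 comparisons. Some lists, among them those of mitochondrial ribosomal proteins (which took in MRP8) and proteasome genes, were drawn by a pattern of gene names. The function of each such member was not checked. The median log2 ratio of a list was ranked among 10000 random lists of the same size, matched on mean signal in 10 groups, and a list was called apart among the lowest 0.5% or the highest 0.5%. Of 312 such ranks, 91 passed, against 3.12 given by the rule for random lists; lists share members and genes are not independent, so these are descriptions of the arrays and not tests. Each was recomputed under 6 alternatives: loess within blocks, median centring, plain subtraction, no background correction, the authors' deposited values and unmatched random lists. Of the 91, 79 kept their call with loess within blocks. Lists that were not called apart in a comparison are not described for it, and 1 list is not reported here.

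The named genes were, for each older generation against the 1st, the 12 highest and 12 lowest features past 2-fold with 1 gene name and signal above background in at least one channel. For differences between generations they were the 8 highest and 8 lowest, and for the shared direction the 6 highest and 6 lowest by their smallest ratio. From each list called apart, or kept for checking labels, the 4 members with the largest absolute log2 ratio were added; some of them are left unnamed in the text. Fewer features were named where fewer passed 2-fold.

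The fixed alternatives were median centring in place of loess, plain subtraction of the blank mean, no background correction, the authors' deposited values, no filter on dim features, a filter on both channels, a threshold of 1.5-fold, direct comparison of quantile-normalised Cy3 channels for differences between generations, and random lists not matched on signal. After the data had been seen, 4 were added: loess within each print block (also for the lists), the authors' deposited values centred within blocks, only features whose signal the authors kept in both channels, and leaving out features with an unstable 1st generation signal.

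The steps were tested on simulated data with 5792 features and 200 changed ones. In the simulation of the 11th generation against the 1st, a true log2 ratio of 2 passed 2-fold for 39 of 50 features and one of 4 for 48 of 50, and the median for a true 4 was 3.34, since the offset pulls ratios of dim spots towards 0. There was 1 false call. The simulated noise was set small beside 2-fold and held no dye effect of probes, so the number of false calls on the real arrays cannot be read from it. Of 20 random lists of 20 features shifted by 1 on the log2 scale, 20 were called apart, and of 20 that were not shifted, 1 was. For the shared direction, arrays were simulated with a common 1st generation signal and no effect, with noise taken from the difference of the 7th and 4th generation; the observed block medians were added to a second simulation after the data had been seen.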

Results

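The transcripts of replicatively ageing budding yeast were measured on 3 two-colour oligonucleotide arrays, one each for cells of the 4th, 7th and 11th generation of strain BY4742, a haploid laboratory strain of mating type alpha. Each array held total RNA of the older cells in the Cy3 channel and RNA of 1st generation cells in the Cy5 channel. There was 1 array per generation, with no replicate array and no dye swap, so every value below is the value of a single array, no error can be given, and the number of arrays limits the precision. In values against the 1st generation, a dye effect of a probe cannot be told apart from an effect of generation. Each array carried 5792 features for yeast genes. Median raw signals in the Cy5 channel were 177, 161 and 162 on the arrays of the 4th, 7th and 11th generation, and those in the Cy3 channel were 523, 496 and 591. Signal above the blank spots in at least one channel was found for 5659, 5567 and 5703 features. Counts are of features at least 2-fold higher or lower. A gene list was called apart from other features when its median log2 ratio lay among the lowest 0.5% or the highest 0.5% of 10000 random lists of like signal.

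The labels of the samples were set against marker genes. The a-specific genes, which an alpha strain should keep off, were dim in both channels, with median ranks between percentile 14 and 20.7 of all features. The alpha-specific genes were bright in the 1st generation channel, with median ranks between percentile 92.5 and 94.2. Of the genes deleted in BY4742, LEU2 gave no signal above the blank spots in either channel of any array. LYS2 gave none in the Cy3 channel but was above the limit in Cy5 on all 3 arrays, with raw signals of 38.2, 30.6 and 32.8. URA3 was above it in Cy5 on all 3 arrays, at 38.9, 34.4 and 41.6, and in Cy3 on 2 of them. HIS3 gave raw Cy5 signals of 435, 430 and 356, and the place of its probe relative to the deleted part of the gene is not known, so HIS3 tests nothing here.

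The log2 ratios depended on the place of a spot. The array is divided into 16 print blocks, and the median log2 ratio of features in even blocks exceeded that in odd blocks by 0.45, 0.45 and 0.44 on the 3 arrays after loess normalization over the whole array. In the authors' deposited values the offset was 0.81, 0.79 and 0.83. Of the features at least 2-fold higher at the 4th generation, 205 of 237 lay in even blocks, and of those at least 2-fold lower 183 of 206 lay in odd blocks. At the 11th generation these numbers were 310 of 419 and 270 of 314. The offset was of like size on all arrays, so most of it drops out of differences between arrays. Each gene group set against the 1st generation is therefore given below with its median after loess within each block, an alternative added after the data had been seen.

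**Figure D1:**
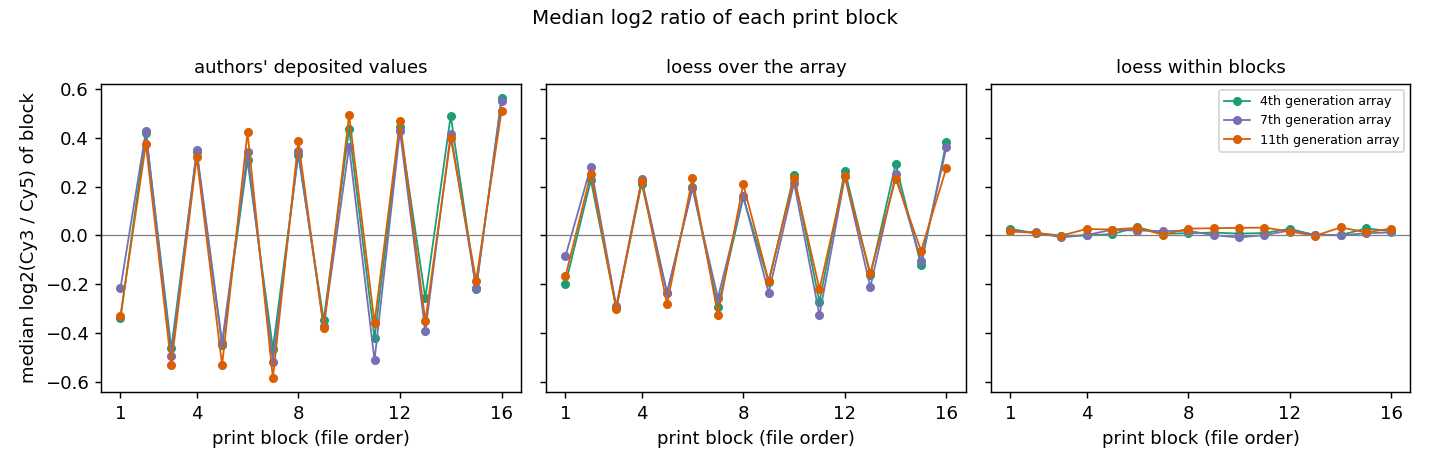
Median log2(Cy3 / Cy5) of the features of each of the 16 print blocks (x axis, in file order) on the 3 arrays (colours), in the authors' deposited values (left), after loess over the array (middle) and after loess within blocks (right). Blocks alternate between higher and lower medians in the left and middle panels, with offsets of 0.81, 0.79 and 0.83 on the left and 0.45, 0.45 and 0.44 in the middle.

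At the 4th generation, against the 1st, cells had 10.7-fold more transcript of NCE103 (YNL036W), the carbonic anhydrase of yeast, and 5.77-fold more of SIT1 (YEL065W), a siderophore-iron transporter. Transcripts of the co-chaperone SIS1, the DNA-damage-inducible ribonucleotide reductase subunit RNR3, the eisosome protein FHN1 and the protein-sorting factor CUR1 were 5.85-fold, 5.74-fold, 5.61-fold and 5.53-fold higher. The uncharacterised YBR085C-A and YHL048C-A, the cell wall protein HSP150, the polyamine transporter TPO4, the S-adenosylmethionine synthetase SAM2 and the vacuolar protease PRB1 were between 4.48-fold and 6.65-fold higher. The lowest were YKR075C at 9.03-fold lower, the hexose transporter HXT4 at 7.02-fold lower and the histidine biosynthesis gene HIS4 at 5.88-fold lower. They were followed by NFG1, the DNA polymerase alpha subunit POL12, YOL013W-B, the alpha-agglutinin SAG1 (YJR004C), the glycine cleavage gene GCV2, the small heat shock protein HSP26, the cell fusion gene FUS1, the permease FCY2 and TAR1, between 4.38-fold and 5.41-fold lower.

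Several gene groups stood above or below the other features at the 4th generation. Iron regulon genes had a median log2 ratio of 0.70 (0.78 within blocks), with 7 of 16 members at least 2-fold higher, among them TIS11, an mRNA-binding protein of the iron response, at 3.78-fold and the heme oxygenase HMX1 at 2.88-fold. Cell wall integrity targets had a median of 0.66 (0.59 within blocks), with the protease YPS1 at 3.73-fold and the wall protein SED1 at 3.00-fold, and 4 of 12 were at least 2-fold higher. Proteasome genes had a median of 0.61 (0.47 within blocks), 9 of 34 were at least 2-fold higher, and PRE1 was 2.78-fold higher. Ribosome biogenesis genes had a median of 0.43 (0.37 within blocks), 13 of 92 were at least 2-fold higher, and NOP53 was 3.29-fold higher, while RLP24 was 3.16-fold higher, a log2 ratio of 1.66 that became 1.06 within blocks. Heat shock factor targets had a median of 0.48, 0.40 within blocks but -0.079 in the authors' deposited values, lost their call there and after median centring, and held both HSP42 at 4.10-fold higher and HSP26 at 4.88-fold lower. General stress targets, which share HSP26, HSP42 and other chaperone genes with that list, had a median of 0.40 (0.32 within blocks), with 5 of 24 higher and 2 lower, and lost their call after median centring, at 0.36. The cold-shock mannoproteins and seripauperins, cell wall proteins of cold and low oxygen, had a median of 0.39 (0.30 within blocks), with TIR1 at 3.27-fold and PAU9 at 3.04-fold higher, and lost their call after median centring, at 0.33. On the low side, purine biosynthesis genes had a median of -0.92 (-0.80 within blocks), 7 of 14 were at least 2-fold lower, and ADE2 was 3.06-fold and MTD1 2.81-fold lower. Pheromone-induced genes had a median of -1.01 (-0.81 within blocks), all 9 were below 0, and AGA1, which anchors an agglutinin to the wall, was 4.23-fold and PRM1 3.72-fold lower. Alpha-specific genes had a median of -0.95, and their call was lost within blocks at -0.74, while STE3, the receptor for a-factor, was 2.02-fold lower, a log2 ratio of -1.01 that became -0.79 within blocks and -0.85 after median centring. Hexose transporters had a median of -0.50 (-0.22 within blocks, -1.43 in the authors' deposited values), with HXT1 3.36-fold lower, and cytosolic ribosomal proteins had a median of -0.17 (-0.16 within blocks, -0.79 in the authors' deposited values), with 7 of 137 at least 2-fold lower. Glycolysis and fermentation genes had a median of 0.50, which was 0.07 within blocks, -0.042 after median centring and -0.48 in the authors' deposited values, so no direction can be given for them. In the authors' deposited values the medians of proteasome genes, iron regulon genes, seripauperins and alpha-specific genes were 0.27, 1.14, 0.85 and -1.48. Under plain subtraction of the blank signal those of iron regulon genes, seripauperins, pheromone-induced genes and hexose transporters were 1.15, 0.79, -1.54 and -0.94. After median centring hexose transporters were at -1.04 and cytosolic ribosomal proteins at -0.39.

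In all, 237 features were at least 2-fold higher and 206 lower at the 4th generation, out of 5659, with no test possible on 1 array. Loess within blocks gave 123 and 141, of which 98 and 102 were among the former, and median centring gave 389 and 215. The authors' deposited table marks 590 features as up and 538 as down. Single values moved by over 1.5-fold within blocks for SIS1 (log2 ratio 2.55 to 1.93), and in the authors' deposited values for YHL048C-A (2.45 to 5.06), RNR3 (2.52 to 3.29), FHN1 (2.49 to 3.31), TPO4 (2.25 to 3.00), HMX1 (1.53 to 2.15), PRM1 (-1.89 to -2.61) and HSP150 (2.29 to 1.56), and under plain subtraction of the blank signal for POL12 (-2.35 to -3.05).

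At the 7th generation, NCE103 was 14.3-fold higher than in the 1st, and CIT2, the peroxisomal citrate synthase, was 6.90-fold higher. YBR085C-A, FHN1, YHL048C-A, SIT1, PRB1 and TIS11 were between 5.02-fold and 6.56-fold higher, and HSP150, the calmodulin-dependent kinase CMK2, DIA1 and YHR138C were between 4.48-fold and 4.82-fold higher. The lowest were YKR075C at 9.68-fold lower, SAG1 at 6.83-fold lower and FUS1 at 5.62-fold lower. YOL013W-B, NFG1, HXT4, the glucanase DSE4, HIS4, AGA1, GCV2 and GWT1, an enzyme of GPI anchor synthesis, were between 3.99-fold and 5.50-fold lower. RPL22B, a ribosomal protein gene, was 4.65-fold lower, but its 1st generation signal itself differed 3.16-fold between arrays.

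By group at the 7th generation, iron regulon genes had a median of 0.80 (0.66 within blocks), 7 of 16 were at least 2-fold higher, and the cell wall iron-retention protein FIT2 was 3.62-fold and the siderophore transporter ARN2 2.58-fold higher. Cell wall integrity targets had a median of 0.73 (0.63 within blocks), with YPS1 at 3.58-fold. Sulfate assimilation and methionine biosynthesis genes had a median of 0.66 (0.58 within blocks), 5 of 20 were at least 2-fold higher, and SAM2 was 3.79-fold, the methionine permease MUP1 3.39-fold and methionine synthase MET6 2.71-fold higher. Proteasome genes had a median of 0.64 (0.47 within blocks) with 10 of 34 at least 2-fold higher, ribosome biogenesis genes 0.41 (0.33 within blocks) with 15 of 92 higher and 1 lower, and general stress targets 0.40 (0.35 within blocks, no longer apart after median centring, at 0.48). The cold-shock mannoproteins and seripauperins had a median of 0.58 (0.46 within blocks, but 1.22 under plain subtraction and in the authors' deposited values), 8 of 25 were at least 2-fold higher, and PAU9 was 3.69-fold and TIR1 3.63-fold higher. Alpha-specific genes had a median of -1.40 (-1.24 within blocks), 3 of 4 were at least 2-fold lower, and STE3 was 2.79-fold lower. Pheromone-induced genes had a median of -0.96 (-0.83 within blocks, -1.68 under plain subtraction), with PRM1 at 3.89-fold lower, and purine biosynthesis genes had a median of -0.79 (-0.63 within blocks), with MTD1 at 3.26-fold lower. Cytosolic ribosomal proteins had a median of -0.26 (-0.17 within blocks, -0.94 in the authors' deposited values), with RPS9A 3.49-fold lower. Hexose transporters had a median of -0.27, and their call was lost within blocks, at -0.15, and against random lists not matched on signal. Their median was -1.06 after median centring, -1.22 under plain subtraction and -1.44 in the authors' deposited values. In the latter proteasome genes were at 0.24 and pheromone-induced genes at -1.48, and after median centring cytosolic ribosomal proteins were at -0.51.

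The 7th generation array gave 254 features at least 2-fold higher and 198 lower, out of 5567. Loess within blocks gave 129 and 113, of which 105 and 80 were among the former, and median centring gave 412 and 232. The authors' deposited table marks 584 up and 549 down. In the authors' deposited values YHL048C-A moved from 2.54 to 4.78, FHN1 from 2.57 to 3.53, YHR138C from 2.16 to 2.83, FUS1 from -2.49 to -3.16, HIS4 from -2.18 to -2.79, GWT1 from -2 to -2.65, PRM1 from -1.96 to -2.82 and HSP150 from 2.27 to 1.46. Under plain subtraction YOL013W-B moved from -2.46 to -3.06.

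At the 11th generation the differences from the 1st generation were wider: NCE103 was 27.0-fold higher, the stress-induced ribosome-associated TMA10 (YLR327C) 23.5-fold and CIT2 16-fold higher. Iron genes were among the highest, with SIT1 at 12.8-fold, FIT2 at 11.6-fold and TIS11 at 10.7-fold, and YBR085C-A, MNC1, FHN1, DPI8, the plasma membrane protein PUN1 and YHR138C were between 9.92-fold and 14.9-fold higher. The lowest was SAG1 at 11.6-fold lower, then the branched-chain amino acid enzyme ILV3 at 8.10-fold lower. FUS1, NFG1, the acid phosphatase PHO3, AGA1, DSE4, the cell separation gene EGT2, YOL013W-B, HXT4 and the cytochrome c gene CYC1 were between 5.75-fold and 6.69-fold lower. The hexose transporter HXT7 was 7.03-fold lower, but its 1st generation signal differed 3.04-fold between arrays.

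Grouped by list at the 11th generation, the cold-shock mannoproteins and seripauperins had a median of 1.83 (1.64 within blocks, 2.48 under plain subtraction), with 21 of 26 members at least 2-fold higher. PAU9 was 7.95-fold, TIR4 7.03-fold, TIR1 6.40-fold and DAN1 at least 6.31-fold higher, a bound because its 1st generation signal was not above the blank spots. Iron regulon genes had a median of 1.44 (1.41 within blocks, 2.26 under plain subtraction, 2.41 in the authors' deposited values), with 13 of 16 at least 2-fold higher and FIT3 at 8.25-fold. Cell wall integrity targets had a median of 1.04 (0.89 within blocks), with YPS1 at 4.17-fold. General stress targets had a median of 0.76 (0.70 within blocks), with HSP12 at 6.44-fold and DDR2 at 3.89-fold. Stationary phase genes, which share HSP12 and SPI1 with the stress list, had a median of 0.68 (0.79 within blocks, 2.10 under plain subtraction, 2.07 in the authors' deposited values), and 8 of 18 were at least 2-fold higher, among them SPG4 at 9.27-fold, the vitamin B6 gene SNZ1 at 8.06-fold and the pyruvate carrier subunit MPC3 at 4.49-fold. Proteasome genes had a median of 0.68 (0.61 within blocks), with PRE1 at 3.05-fold. Sulfate assimilation and methionine biosynthesis genes had a median of 0.61 (0.57 within blocks), with MET16 at 4.07-fold. Glyoxylate cycle and gluconeogenesis genes had a median of 0.57 (0.48 within blocks, 1.32 in the authors' deposited values), in which CIT2 and PCK1, the gluconeogenic carboxykinase at 4.12-fold, were the 2 of 11 past 2-fold; the call was lost under plain subtraction of the blank signal and against random lists not matched on signal. Peroxisomal beta-oxidation genes had a median of 0.48 (0.45 within blocks, 1.16 in the authors' deposited values), with the auxiliary enzyme SPS19 at 2.11-fold the 1 of 17 past 2-fold, and lost their call against random lists not matched on signal. Mitochondrial ribosomal proteins had a median of 0.46 (0.55 within blocks), with 12 of 67 at least 2-fold higher and MRPL36 at 4.10-fold. Proteasome genes were at 0.32 in the authors' deposited values, and under plain subtraction sulfate assimilation genes were at 0.98, glyoxylate cycle genes at 0.90 and peroxisomal beta-oxidation genes at 0.89.

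On the low side at the 11th generation stood the 4 alpha-specific genes, all at least 2-fold lower, with a median of -2.36 (-2.10 within blocks, -3 in the authors' deposited values). Besides SAG1, the pheromone gene MF(ALPHA)2 was 5.54-fold, STE3 4.76-fold and MF(ALPHA)1 2.52-fold lower. Pheromone-induced genes had a median of -0.86 (-0.68 within blocks, -1.75 under plain subtraction, -1.34 in the authors' deposited values), with 4 of 9 at least 2-fold lower. Purine biosynthesis genes had a median of -0.99 (-0.78 within blocks), with ADE2 at 2.54-fold lower. The phosphate regulon, which held both PHO5 at 3.17-fold lower and PHO89 at 3.15-fold higher, had a median of -0.49 and lost its call within blocks, at -0.36, and in the authors' deposited values, at -0.88. Haploid-specific genes had a median of -0.73 with the pheromone desensitisation factor SST2 at 4.40-fold lower, and lost their call within blocks at -0.52.

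The counts at the 11th generation were 419 features at least 2-fold higher and 314 lower, out of 5703, and 328 and 219 within blocks, of which 258 and 156 were among the former. The authors' deposited table marks 849 up and 787 down. In the authors' deposited values SPG4 moved from 3.21 to 5.39, SPS19 from 1.08 to 2.59, DDR2 from 1.96 to 3.89, SNZ1 from 3.01 to 4.04, CYC1 from -2.52 to -3.58, TIR4 from 2.81 to 3.81, MF(ALPHA)2 from -2.47 to -3.35, ILV3 from -3.02 to -3.84, FUS1 from -2.74 to -3.48, YHR138C from 3.31 to 4.06, FHN1 from 3.49 to 4.19, HSP150 from 2.22 to 1.2, NCE103 from 4.75 to 4.04, FIT3 from 3.04 to 2.36 and CIT2 from 4.00 to 3.37. Under plain subtraction of the blank signal MNC1 moved from 3.68 to 4.31, and DAN1, for which only a bound holds, from 2.66 to 6.42.

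**Figure D2:**
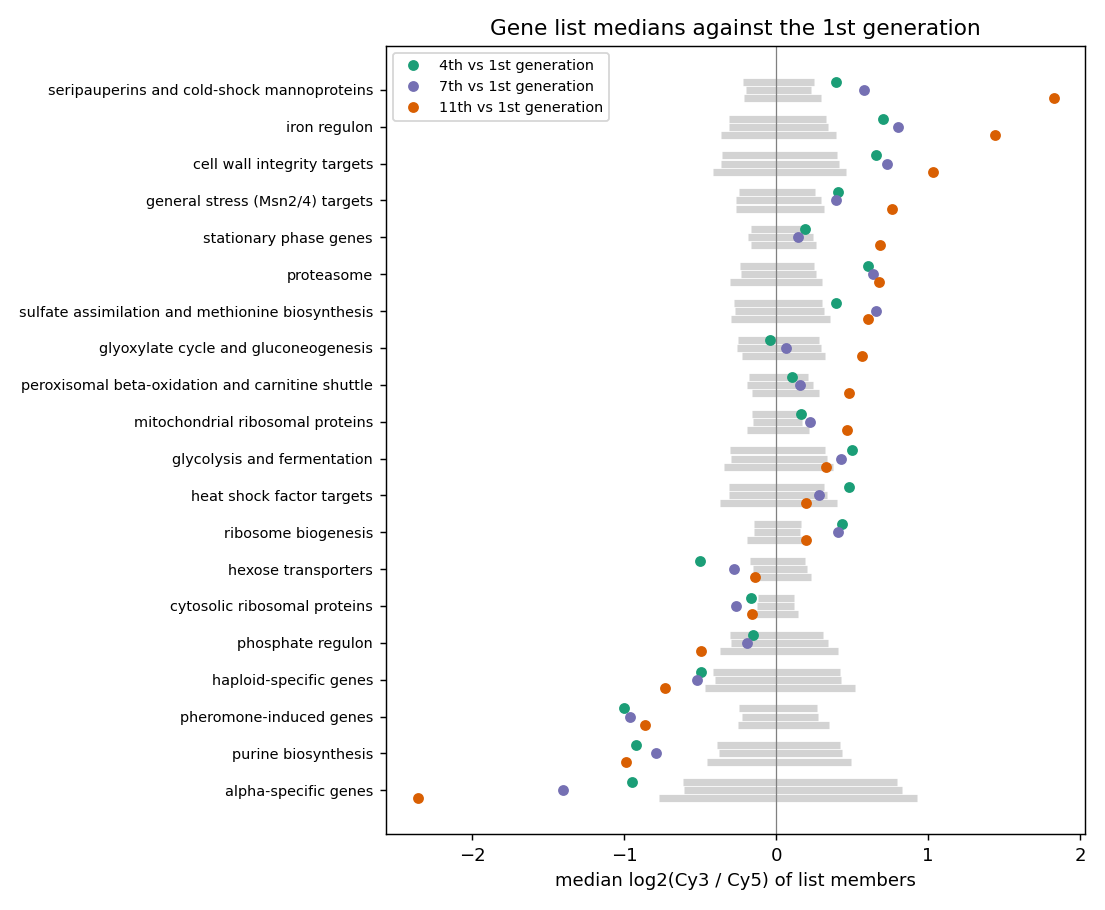
Median log2(Cy3 / Cy5) (x axis) of each gene list reported here that was called apart on at least one array against the 1st generation, for the 3 generations (coloured points), with the central 95% of matched random lists as grey bars. The seripauperins and cold-shock mannoproteins lie highest at 1.83 and the alpha-specific genes lowest at -2.36, both on the 11th generation array; glycolysis is given no direction at the 4th generation, since its median is -0.042 after median centring.

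Across the 3 generations, NCE103, YBR085C-A, SIT1, FHN1, YHL048C-A and HSP150 had the highest smallest ratio, each at least 4.67-fold higher on every array. NFG1, YOL013W-B, SAG1, FUS1, HXT4 and HIS4 were each at least 4.52-fold lower on every array. In total 156 features were at least 2-fold higher and 112 lower on all 3 arrays, out of 5546 measured on each, and 82 and 74 with loess within blocks. Median centring gave 247 and 127, and the authors' deposited values centred within blocks gave 206 and 243. Arrays simulated with a shared 1st generation channel and no effect had 0 in either direction, also with the observed block medians added. Independent lists of these sizes would share 0.818 and 0.416. The simulated noise had the SD of the difference between the 7th and 4th generation, 0.178, so 2-fold lay far outside it and a result of 0 was nearly fixed in advance. A dye effect of a probe drops out of that difference, so the simulation lacks it. The simulation also leaves out real differences, and independence leaves out the shared channel and the block offset, so neither excess is a measure of a shared response. No feature was at least 2-fold higher on one array and at least 2-fold lower on another, while 373 passed 2-fold at the 11th generation alone; whether these differed between generations was not tested. Of the 237 features higher at the 4th generation 197 were also higher at the 7th, and of the 206 lower at the 4th 152 were also lower at the 7th, where independent lists would share 10.9 and 7.35 and both simulations gave 0. Part of each overlap may come from the shared 1st generation channel, or from dye effects of the probes, since the older cells were in Cy3 on all 3 arrays. For the 4th and 11th generation the shared numbers were 165 and 127, against 17.9 and 11.7 for independent lists.

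The correlation of log2 ratios across features was 0.953 between the 4th and 7th, 0.838 between the 7th and 11th and 0.777 between the 4th and 11th generation. Genes are not independent replicates, and the shared 1st generation channel alone gave a correlation of 0.486 to 0.494 in a simulation with no effect. With the observed block medians added the simulation gave 0.826 to 0.832, above the value between the 4th and 11th generation. The covariances of 0.318, 0.349 and 0.325 exceeded the 0.0150 to 0.0152 of the first simulation and the 0.0806 to 0.0832 of the second. Within blocks the correlations were 0.941, 0.810 and 0.735.

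Between the 4th and 7th generation, 9 features were at least 2-fold higher at the 7th and 6 lower, out of 5550. The counts were 83 and 68 with the Cy3 channels compared directly, 44 and 41 under plain subtraction and 31 and 21 in the authors' deposited values. HSP26 was 2.24-fold higher, the replication helicase subunit MCM3 2.06-fold, ASI2 2.05-fold and POL12 2.03-fold higher, while the mannosyltransferase PMT5 was 2.09-fold, YPR063C 2.03-fold and the mitotic cyclin CLB2 2-fold lower. When the Cy3 channels were compared directly, the log2 differences of MCM3, ASI2 and POL12 were -0.11, -0.0069 and -0.082, and those of PMT5 and CLB2 -2.07 and -1.88. Within blocks MCM3, POL12, PMT5 and CLB2 did not reach 2-fold, at 0.90, 0.89, -0.93 and -0.92. Nor did MCM3, POL12, ASI2 and YPR063C after median centring, at 0.90, 0.89, 0.81 and -0.92, POL12 without background correction, at 0.95, and CLB2 in the authors' deposited values, at -0.89. ASI2 was at 1.80 in the authors' deposited values and PMT5 at -1.70 under plain subtraction. MOB1, RAP1, ATP5 and YDR476C were between 2.31-fold and 2.80-fold higher and RPS13, BMS1 and SLG1 between 2.88-fold and 3.49-fold lower, but the 1st generation signal of these genes differed between 2.12-fold and 5.83-fold among arrays. With the Cy3 channels compared directly MOB1, RAP1, RPS13, BMS1, SLG1 and ATP5 were at 0.17, 0.26, -0.021, -0.59, 0.14 and -0.93, and YDR476C was at 2.51. Leaving out all features with such a 1st generation signal gave 8 in place of 15, and median centring gave 22 higher and 6 lower.

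Small shifts of list medians were seen between the 4th and 7th generation, although the members of a list did not all move alike. The alpha-specific genes had a median difference of -0.45 (-0.47 within blocks), with STE3, SAG1 and MF(ALPHA)2 each near that value and MF(ALPHA)1 at -0.02, or 0.62 with the Cy3 channels compared directly. Heat shock factor targets had a median of -0.15 (-0.17 within blocks, -0.27 in the authors' deposited values), with the chaperones HSP78 at 1.85-fold and HSP82 at 1.75-fold lower, and G2/M genes a median of -0.19 (-0.17 within blocks), with the transcription factor SWI5 at 1.37-fold lower. The seripauperins and cold-shock mannoproteins had a median of 0.17 (0.17 within blocks, 0.30 under plain subtraction), mitochondrial ribosomal proteins 0.11 (0.12 within blocks) and the phosphate regulon 0.18 (0.12 within blocks, but 0.05 after median centring and 0.02 in the authors' deposited values, no longer apart in either). Glycolysis, haploid-specific genes and histones, with medians of -0.10, -0.15 and 0.24, lost their calls within blocks, at -0.028, -0.092 and 0.13, and glycolysis lost it under 5 of the 6 alternatives.

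From the 7th to the 11th generation, TMA10 was 7.13-fold, PUN1 7.11-fold, SPG4 5.33-fold and HSP12 4.92-fold higher. SNZ1 was 4.70-fold, the iron-responsive LSO1 4.12-fold and PCK1 3.94-fold higher. DAN1 was among the highest too, but its 1st generation signal was not above the blank spots on either array, so no fold is given. The aromatic amino acid catabolic genes ARO10 and ARO9 were 4.93-fold and 3.31-fold lower, TPO4 3.53-fold, the methyltransferase EFM2 2.84-fold, the leucine biosynthesis gene LEU1 2.70-fold and YDL038C 2.66-fold lower. HAS1 at 3.58-fold and UTR4 at 3.27-fold lower had a 1st generation signal that differed 5.22-fold and 3.01-fold between arrays, and the Cy3 channels compared directly gave 0.26 for HAS1.

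By list from the 7th to the 11th generation, seripauperins and cold-shock mannoproteins had a median difference of 1.00 (0.97 within blocks), with PAU5 at 3.51-fold, and iron regulon genes 0.96 (0.86 within blocks), with FIT3 at 3.23-fold. Stationary phase genes had 0.62 (0.77 within blocks, 1.02 under plain subtraction, 1.2 in the authors' deposited values) and histones 0.55 (0.58 within blocks, but 0.28 after median centring and 0.23 in the authors' deposited values). Glyoxylate cycle genes had 0.50 (0.49 within blocks, 0.83 under plain subtraction, 0.92 in the authors' deposited values) and general stress targets 0.48 (0.50 within blocks). Smaller positive medians were those of mitochondrial ribosomal proteins at 0.29 (0.34 within blocks), peroxisomal beta-oxidation genes at 0.28 (0.30 within blocks), the tricarboxylic acid cycle at 0.29 (0.28 within blocks, 0.16 in the authors' deposited values), with IDH1 at 3.52-fold, and autophagy genes at 0.24 (0.26 within blocks), with ATG5 at 1.88-fold. Of these, the tricarboxylic acid cycle kept its call under 2 of the 6 alternatives, and peroxisomal beta-oxidation lost it under plain subtraction of the blank signal and in the authors' deposited values, at 0.46 and 0.47. Alpha-specific genes had -0.77 (-0.94 within blocks), branched-chain amino acid biosynthesis -0.62 (-0.54 within blocks), M/G1 genes -0.60 (-0.58 within blocks), cytosolic aminoacyl-tRNA synthetases -0.33 (-0.38 within blocks) and ribosome biogenesis -0.25 (-0.26 within blocks). Calls were lost within blocks for hexose transporters at 0.22, 0.39 under plain subtraction, which kept theirs under 1 of the 6 alternatives, for COS and Y prime helicase genes at 0.33, which also lost theirs against random lists not matched on signal and were at 0.76 in the authors' deposited values, and for zinc regulon genes at -0.43, -0.19 within blocks, and G1/S genes at -0.32. In all 103 features were at least 2-fold higher and 34 lower, out of 5556, and 107 and 31 within blocks, while plain subtraction of the blank signal gave 375 in all. With the Cy3 channels compared directly, TPO4 moved from -1.82 to -3.13, EFM2 from -1.5 to -2.48, LSO1 from 2.04 to 2.86, SPG4 from 2.41 to 3.06 and UTR4 from -1.71 to -0.28, and in the authors' deposited values ARO9 moved from -1.72 to -2.46.

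From the 4th to the 11th generation, TMA10 was 11.3-fold, HSP26 7.90-fold, SNZ1 6.19-fold and the transaldolase NQM1 6.03-fold higher. SPG4 was 5.81-fold, DPI8 5.67-fold and PUN1 5.49-fold higher. DAN1 was again among the highest, with no fold given for the same reason and raw Cy3 signals of 58.6, 73.0 and 1045 on the 3 arrays. ARO10 was 4.63-fold, TPO4 4.60-fold, the zinc transporter ZRT1 3.96-fold, ARO9 3.78-fold, LEU1 3.27-fold, the ribonucleotide reductase subunit RNR1 3.19-fold and YDL038C 3.18-fold lower. HAS1 was 4.11-fold lower, but the Cy3 channels compared directly gave a log2 difference of 0.022 for it.

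The groups that differed between the 4th and 11th generation covered metabolism, stress, mating and the cell cycle. Seripauperins and cold-shock mannoproteins had a median difference of 1.23 (1.11 within blocks), with 19 of 25 at least 2-fold higher, and iron regulon genes 0.81 (0.75 within blocks), with FIT3 at 5.37-fold. Histones had a median of 0.75 (0.74 within blocks, 0.38 after median centring, 0.29 in the authors' deposited values), with HHT1 at 2.29-fold and HHT2 at 2.28-fold, and stationary phase genes 0.72 (0.80 within blocks, 1.28 under plain subtraction, 1.57 in the authors' deposited values). General stress targets had 0.49 (0.49 within blocks), glyoxylate cycle and gluconeogenesis genes 0.48 (0.53 within blocks, 1.15 under plain subtraction, 1.31 in the authors' deposited values), with PCK1 at 4.65-fold and acetyl-CoA synthetase ACS1 at 2.67-fold. ATP synthase genes had 0.45 (0.41 within blocks), in which ATP5, the 1 of 14 past 2-fold, had an unstable 1st generation signal and was at 0.25 with the Cy3 channels compared directly. Mitochondrial ribosomal proteins had 0.42 (0.45 within blocks), the tricarboxylic acid cycle 0.41 (0.41 within blocks, 0.24 and no longer apart in the authors' deposited values), with the isocitrate dehydrogenase genes IDH1 at 3.55-fold and IDH2 at 2.41-fold. IDH2 did not reach 2-fold in the authors' deposited values, at 0.97, or with the Cy3 channels compared directly, at 0.98. Peroxisomal beta-oxidation genes had 0.38 (0.33 within blocks, 0.64 in the authors' deposited values). Hexose transporters had 0.27, with HXT2 at 3.13-fold (log2 difference 1.64, 1.05 in the authors' deposited values), but kept their call only within blocks, at 0.29, out of the 6 alternatives. Amino acid degradation genes had a median of 0.39 (0.36 within blocks) with BAT2 at 2.51-fold higher, although ARO9 and ARO10, 2 of its 17 members, were among the lowest of all features.

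Lower at the 11th than at the 4th generation were the alpha-specific genes with -1.23 (-1.29 within blocks) and MF(ALPHA)2 at 3.00-fold lower, and branched-chain amino acid biosynthesis with -0.84 (-0.74 within blocks) and ILV3 at 2.68-fold lower. With the Cy3 channels compared directly MF(ALPHA)1 moved from -0.75 to 0.06. M/G1 genes had -0.61 (-0.61 within blocks), with the replication licensing gene CDC6 at 1.80-fold lower, and G2/M genes -0.57 (-0.53 within blocks), with CLB2 at 2.22-fold and SWI5 at 2.01-fold lower, or -0.99 within blocks. G1/S genes had -0.33 (-0.38 within blocks), with the cyclin CLB6 at 1.87-fold lower, but lost their call after median centring, under plain subtraction and in the authors' deposited values. Heat shock factor targets had -0.38 (-0.34 within blocks), with SIS1 at 1.99-fold lower but HSP26 higher, cytosolic aminoacyl-tRNA synthetases -0.38 (-0.40 within blocks, -0.60 in the authors' deposited values) and ribosome biogenesis -0.27 (-0.28 within blocks). In total 150 features were at least 2-fold higher and 50 lower, out of 5645; loess within blocks gave 150 and 51, of which 140 and 44 were among the former. Direct comparison of the Cy3 channels gave 249 and 113, and in it NQM1 moved from 2.59 to 3.50, TPO4 from -2.20 to -3.48, ARO9 from -1.92 to -2.60, SPG4 from 2.54 to 3.26 and BAT2 from 1.33 to 2.03. In the authors' deposited values the counts were 316 and 137, ACS1 moved from 1.42 to 2.56, SNZ1 from 2.63 to 3.25 and CLB6 from -0.90 to -1.79, and HHT1 and HHT2, at 0.71 and 0.67, no longer reached 2-fold. They were at 0.79 and 0.76 after median centring, and HHT2 was at 0.91 with the Cy3 channels compared directly.

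**Figure D3:**
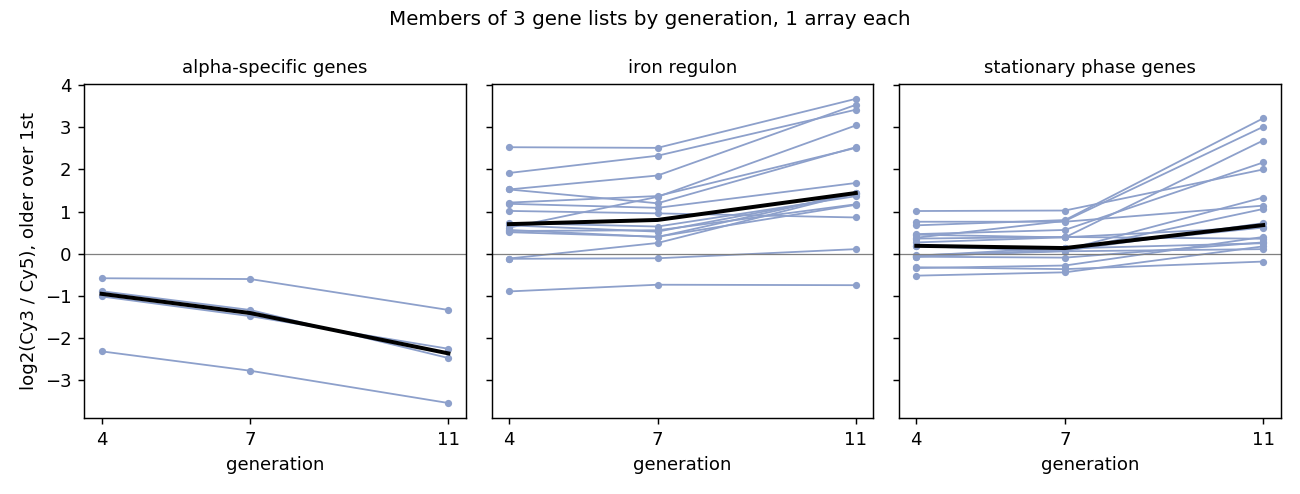
Log2(Cy3 / Cy5) of single genes (thin lines) and their median (thick line) at the 4th, 7th and 11th generation against the 1st, for 3 gene lists, after loess over the array. The alpha-specific median goes from -0.95 to -2.36 and the iron regulon median from 0.70 to 1.44.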

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

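All tests in this part were chosen after the results they weigh had been seen. The rule for opposite directions was widened after a stricter one, 2-fold both ways, had found no feature.

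The small heat shock gene HSP26 was lower than in the 1st generation at the 4th and higher at the 11th, with log2 ratios of -2.29 and 0.69, a difference of 2.98, and ARO9 was higher at the 4th and lower at the 11th, with 1.12 and -0.80, a difference of 1.92. These were the 2 of 236 named features at least 2-fold off on one array and at least 1.5-fold off in the other direction on another, features with an unstable 1st generation signal left aside; the differences were not tested. Within blocks HSP26 still met this rule, at -2.06 and 0.75, but ARO9, at 0.71, 0.49 and -0.91 on the 3 arrays, was 2-fold off on none of them. Of the spots listed as holding no probe, 1 lay above background in both channels on all 3 arrays, with raw Cy5 signals of 66.6, 59.2 and 80.3 and raw Cy3 signals of 151, 145 and 197.

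Log2 ratios against the 1st generation differed between alternating print blocks, with all 8 even blocks above all odd blocks on each array. ACT1, spotted 4 times in odd and 4 times in even blocks, had a Cy5 signal higher in odd blocks by medians of 1.78-fold, 1.96-fold and 1.90-fold on the 4th, 7th and 11th generation arrays. The permutation tests compared means of log2 values, which gave 1.81-fold, 1.79-fold and 1.35-fold. At the 4th and 7th generation the exact permutation p was 0.0286 two-sided, the smallest that 4 against 4 spots allow, and 0.0643 after adjustment over 9 tests. At the 11th, 1 even spot of 27085 left the exact permutation p at 0.486. In Cy3 the odd over even medians were 1.04, 0.964 and 0.996, and the means of log2 values gave 1.03, 0.961 and 0.980 (exact permutation p = 0.343, 0.457 and 0.714), where p cannot show that values did not differ. A different biological response of the genes in odd and even blocks would leave ACT1 with the same ratio in all blocks, but its log2 ratio was higher in even blocks by medians of at least 0.63 on each array, with odd minus even means of -0.69 and -0.77 at the 4th and 7th generation (exact permutation p = 0.0286, 0.0643 after adjustment over 9 tests) and -0.39 at the 11th (exact permutation p = 0.457). An offset of 0.44 or more left after loess over the array argues against an intensity trend as the whole cause, and a candidate explanation is a position effect in the Cy5 channel, tied to the 1.78-fold ratio of ACT1, whose origin in printing, hybridisation or scanning stays open.

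Alpha-specific genes were lower in older cells, although between the 4th and 11th generation MF(ALPHA)1 was at 0.06 with the Cy3 channels compared directly, where STE3, SAG1 and MF(ALPHA)2 were between -1.56 and -1.16. Block position as the whole cause is argued against by a median of -2.10 within blocks at the 11th generation, and a fixed dye effect of the probes by a median difference of -1.23 between the 11th and 4th generation, in which such an effect drops out; for the -0.95 at the 4th generation, dye and generation cannot be told apart, because no array had the dyes swapped. Repression by a1-alpha2 after loss of silencing at the HMR locus would have lowered other haploid genes alike, but 8 a1-alpha2 targets that pheromone does not induce had a median of 0.02 within blocks at the 11th generation, with 7 of them, among them STE4 and STE5, between -0.39 and 0.45 and HO, added to the set after the other 7 had been computed, at -2.28. After loess over the whole array the median of these 8 was -0.17. The HMRA1 feature, named for the HMR locus itself, showed no rise. Its log2 ratios were -0.12, -0.07 and -0.07 at the 4th, 7th and 11th generation (-0.12, -0.08 and -0.09 within blocks). A dim feature would also lie near 0 because of the offset, so this 1 feature does not decide the matter. The haploid-specific list, fixed beforehand, had a median of -0.73 at the 11th generation (-0.52 within blocks, where its call was lost). It shares STE4, STE5, STE18, RME1 and AXL1 with the 8 targets. After loess over the whole array these shared genes were between -0.68 and 0.08 at the 11th generation, all above the list median. The low median of the list thus came from its other members. The 0.02 therefore speaks for these targets only. Lower basal pheromone signalling may account for part of the difference at the 4th generation, where the pheromone-induced list lay at percentile 0 of random lists. For the pheromone-induced list, too, dye and generation cannot be told apart on that array. That list had a median difference of 0.07 between the 4th and 11th generation, so it leaves the later part open. Its medians at the 4th, 7th and 11th generation were -1.54, -1.68 and -1.75 under plain subtraction, but -1.29, -1.48 and -1.34 in the authors' deposited values. Whether such signalling fell further after the 4th generation can therefore not be told. Replicative age and the way cells were isolated remain untested as causes of that part.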

How the results depend on the processing

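Loess within print blocks, the authors' values centred within blocks and the omission of features with an unstable 1st generation signal were chosen after seeing the data, as was the filter on features the authors kept; the other alternatives were planned. Each ratio pairs older with 1st generation cells on 1 array, and no paired test pooled over the 3 arrays was run. In such a test the 3 arrays would share any dye effect of the probes, and perhaps 1 RNA preparation of the 1st generation. Totals of features past 2-fold, given below for the 4th, 7th and 11th generation against the 1st, were 443, 452 and 733. They became 1052, 1023 and 1456 with plain subtraction of the blank signal, 1117, 1139 and 1634 with the authors' values, 1485, 1466 and 1898 at 1.5-fold, and 739, 801 and 1293 with the authors' values centred within blocks, while loess within blocks gave 264 and 242 for the 4th and 7th. Features past 2-fold on all 3 arrays numbered 268, against 572, 702, 951 and 449 under the same 4 settings, in that order, and 156 with loess within blocks. For the differences 7th to 4th, 11th to 7th and 11th to 4th generation, the totals of 15, 137 and 200 became 85, 375 and 538 with plain subtraction, 52, 318 and 453 with the authors' values, 68, 586 and 808 at 1.5-fold, 46, 319 and 468 with the authors' values centred within blocks, and 151, 289 and 362 with the Cy3 channels compared directly. The 7th to 4th total was 28 after median centring, with 22 higher and 6 lower, and 8 without features of unstable 1st generation signal. A lower threshold passes more features by construction, and the other causes were not tested. The share of higher features among those counted moved by more than 10 points from 53.5% to 64.4% at the 4th generation and from 60% to 78.6% for 7th to 4th after median centring, from 75% to 64.3% with plain subtraction and to 61.3% at 1.5-fold for 11th to 4th, from 75.2% to 64.3% at 1.5-fold for 11th to 7th, and from 58.2% to 45.9% on all 3 arrays with the authors' values centred within blocks. No background correction and the filters on dim features kept every one of the 7 totals within 1.5-fold.

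Among list calls and features past 2-fold, directions turned for the median of glycolysis at the 4th generation (-0.042 after median centring, -0.48 with the authors' values), for that of heat shock factor targets there (-0.079 with the authors' values), and, with the Cy3 channels compared directly, for ASI2 (-0.0069), ATP5 (-0.93), MCM3 (-0.11), POL12 (-0.082) and SLG1 (0.14) from the 4th to the 7th generation, and for HAS1 (0.26 and 0.022) and HXT7 (0.32 and 0.31) from the 7th and 4th to the 11th. Below 2-fold, signs also turned for MF(ALPHA)1 with the Cy3 channels compared directly, to 0.06 from the 4th to the 11th and 0.62 from the 4th to the 7th generation, for TDH2 at the 4th, from 0.84 to -0.042 after median centring and -0.48 with the authors' values, and for values nearer 0. The cause was not tested, but the 1st generation signal of ATP5, SLG1, HAS1 and HXT7 differed 5.83-fold, 3.45-fold, 5.22-fold and 3.04-fold between arrays. Of the 91 calls of a list in a comparison, 67 were kept under all 6 alternatives. Signal over background limits the dim genes: the offset of 50 draws their ratios towards 0, and for LEU2, LYS2 and URA3 no direction was read.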

Other observations

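The chromosome-end test below was written before its result was seen, but the bootstrap that it is read with was added afterwards, and without it the result would have counted against the explanation; the sets in this part other than the outermost genes were picked after the data had been seen.

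Features named for loci inside the ribosomal DNA repeat region and TAR1, 6 in all, had median log2 ratios of -1.47, -1.36 and -1.76 at the 4th, 7th and 11th generation (-1.39, -1.21 and -1.73 within blocks), with 5, 5 and 4 of them at least 2-fold lower. Ty element features had medians of 0.41, 0.35 and 0.40, which became 0.18, 0.09 and 0.34 within blocks. Mitochondrially encoded features had medians of -0.05, -0.22 and -0.29 (-0.11, -0.32 and -0.29 within blocks). The switching endonuclease gene HO was lower at all generations, with log2 ratios of -1.75, -1.64 and -2.47.

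Genes near telomeres were examined because silencing there can weaken in ageing yeast. The 10 outermost genes of each chromosome arm, without the PAU, DAN, TIR, COS and YRF1 families, had a median difference of 0.06 between the 4th and 11th generation over 253 measured genes, at percentile 97.64 of random lists, outside the highest 0.5% set beforehand. The median needed was 0.07, which lies within the 95% bootstrap interval of the observed one, 0.02 to 0.14, so loss of silencing near telomeres may or may not contribute; the same genes lay at percentile 99.89 from the 7th to the 11th generation and at 44.5 for the 11th against the 1st. With those families included the percentile was 100 from the 4th to the 11th generation, and 30 of 277 genes were at least 2-fold higher. Without them 17 of 253 were, and over all features 150 of 5645. The PAU, DAN and TIR genes are the seripauperins and cold-shock mannoproteins described above, so the values with the families are not separate evidence on position near telomeres.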
